A study of Mus musculus with 17 samples.

How the data were processed

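Single-cell RNA sequencing (Drop-seq, which counts captured transcripts in droplets as unique molecular identifiers, UMIs) was analysed for the kidneys of 17 male C57BL/6 mice in a design of 4 groups. The mice were controls or carried the Ins2 Akita mutation, a change in an insulin gene that gives diabetes, and received vehicle or liraglutide, an agonist of the GLP-1 receptor. Per the labels' protocols, liraglutide was injected under the skin at 50 µg/kg daily for 20 weeks from 6 weeks of age. Per the same protocols, cortex was pressed through sieves, the fraction held on the 70 µm sieve was digested in the cold (4 °C) with a bacterial protease, and each mouse was processed on its own. The replicates are named here by group and by their number in the labels (for example, diabetic vehicle replicate 2).

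The deposited matrices hold raw UMI counts per gene and droplet barcode, 1 matrix per mouse. The deposited values are whole numbers whose totals differ between barcodes. The build GRCm38 and Seurat 3.0.1 are named in the submitters' processing notes. The program that aligned and counted the reads, and whether it used the strand, are not given in the sources used here, so reads of genes that overlap on the genome may have been counted for either. A deposited annotation file names the type of 16015 cells, in 14 cell types given by the authors, and their rules for keeping cells and for naming types are not given in the sources used here. The annotated cells held 601 to 10923 UMIs, 401 to 3020 detected genes and 0.836 to 20.0% mitochondrially encoded UMIs. The authors' deposited table of differences holds a natural log fold change for each gene, cell type and pair of groups, whose base was checked against the matrices. The same table holds a p-value and an adjusted p-value from the authors' comparison of cells, by a test that is not given in the sources used here. It also holds the fraction of each group's cells in which the authors detected the gene.

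From these files, raw UMI counts were summed per mouse and cell type over the annotated cells, so that the mouse was the unit of replication. A mouse entered a cell type with at least 10 of its cells, and a cell type was tested where each group compared had at least 3 such mice. Proximal tubule, endothelial and distal tubule cells met this in all comparisons. Loop of Henle cells and podocytes met it for liraglutide in control mice alone, and the other 9 types were tested for their share of cells and not for expression. Low counts were filtered with filterByExpr (minimum count 10), libraries were scaled by TMM, and 1 robust quasi-likelihood fit of the 4 groups was made per type with edgeR 4.0.16 in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all gene and cell type tests of a comparison together, with a threshold of 0.05 for a call. The comparisons were diabetes (diabetic vehicle against control vehicle), liraglutide in diabetic mice, liraglutide in control mice, and the interaction, which is the difference between the 2 liraglutide comparisons. Means are given as CPM (UMI counts scaled to the size of the library as edgeR computes them) with the standard deviation (SD) over mice, and log2 fold changes with their standard error (SE).

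A set of 27 gene lists was fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Each list with at least 5 tested members was tested in each type with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, which asks if the genes of a list move 1 way on balance. Adjustment was over all lists and types of the comparison. Cell type shares and values per mouse (mitochondrial share, summed CPM of a list, Kap) were compared with exact 2-sided permutation tests of the difference of means. The smallest p these tests can give is 0.0079 for 5 against 4 mice and 0.0286 for 4 against 4. The fold changes of liraglutide in diabetic mice were compared with those of diabetes by their covariance across genes. This was set beside the value simulated with no effect for the shared diabetic vehicle mice (50 simulations) and beside the value with different diabetic vehicle mice in each comparison. Genes are not independent replicates, so no p was computed for it.

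The genes named in the text follow a rule. In the 3 types with the most calls of a comparison, the 5 higher and the 5 lower called genes of smallest p were taken. Where a comparison had under 5 calls, its calls and the 5 smallest unadjusted p were taken. Each called list gave up to 4 members, from the type where its p was smallest. The interaction gave its 3 genes of smallest p, and Ager, Glp1r, Ren1, Slc5a2, Havcr1, Vcam1, Ccl2, Txnip, Kap and Fos were always taken where they passed the filter. Mitochondrially encoded, ribosomal protein and predicted genes were counted and not taken by the first part of the rule. Another 2 genes that the rule takes are not reported here, and they stay in the counts of calls and of list members. Of the 123 named genes, 122 matched a symbol in GENCODE vM21 (GRCm38), from which positions are given. Ctgf matched none, and Atp5o and Ddit3 matched 2 genes each.

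The samples were examined for structure that the groups do not explain. In proximal tubule cells, the first principal component of the deviations from the group means held 26.3% of the variance and set replicate numbers 1 and 2 (early) apart from numbers 3 and above (late). The labels give no date or batch for this, so counts of calls, called lists and values per mouse were also computed within each set of numbers, and named genes are summarised there by their direction. The deposited sample names carry a serial number, lower in all early than in all late mice, whose meaning is not given. By it, both late diabetic liraglutide mice precede both late diabetic vehicle mice. Liraglutide and that serial order cannot be told apart among those mice. Proximal tubule transcripts in other cells were followed through Kap, an abundant proximal tubule transcript that free RNA carries into other droplets. No pair of mice of 1 group held identical counts (0 of 28 pairs).

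The alternatives planned were another normalization (RLE), no filter on low counts and a stricter one (minimum count 30), a fit of the 2 groups compared alone, at least 20 cells per mouse and type, removal of the 5% of cells with the most UMIs in each mouse (doublets), removal of mitochondrially encoded, hemoglobin and proximal tubule list genes before scaling, a proximal tubule free RNA covariate, replicate number as a block, DESeq2 1.42.0, adjustment within each type, and each mouse left out in turn. After seeing the data, an early-late term alone and with the covariate, fits within each set of numbers, cells of 6 to 12% mitochondrial UMIs, cells of 1500 to 3000 UMIs, and genes chosen from a single pair of diabetic vehicle mice were added. The edgeR fit and camera with the preset correlation were tested on simulated counts with known changes before they were run on the files. This covered diabetes in proximal tubule, endothelial and distal tubule cells, and no such test is given for the other comparisons and tests. The simulated genes varied independently, with no early and late sets. With no change simulated camera called 0 lists, where the other splits of the real mice gave a median of 11 in diabetes. In the simulated diabetes comparison, 20.9%, 56.7% and 95.5% of genes changed 1.5-, 2- and 4-fold were recovered among 10715 genes in proximal tubule cells, with 11 false calls of 130. The recovered shares were 7.5%, 37.3% and 87.9% among 4442 genes in endothelial cells (2 false of 91) and 10.4%, 41.8% and 98.5% among 3387 genes in distal tubule cells (3 false of 104). Files were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.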

Results

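Kidney cells of 17 male mice were profiled to follow how diabetes and liraglutide alter the transcripts of kidney cell populations. Each mouse gave 1 droplet library from the sieved cortex, and the libraries fell into 4 groups: control vehicle (5 mice), control liraglutide (4 mice), diabetic vehicle (4 mice) and diabetic liraglutide (4 mice). The matrices held 2137 to 15260 barcodes per mouse, and the cells annotated by the authors numbered 404 (control liraglutide replicate 1) to 1752 (control vehicle replicate 4) per mouse. Those cells held 1174306 to 4770933 UMIs per mouse, with a median per cell of 1848 to 2912 UMIs. Summed over mice, control vehicle held 5824 cells and 15895022 UMIs, control liraglutide 3626 cells and 9428862 UMIs, diabetic vehicle 3803 cells and 11030008 UMIs, and diabetic liraglutide 2762 cells and 7985948 UMIs.

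Proximal tubule cells, which take back most of the filtered solutes, made up 12361 of the 16015 annotated cells (77.2%). Endothelial cells followed with 1595 cells (9.96%), distal tubule cells, led by Calb1 and the salt transporter Slc12a3, with 950 (5.93%), loop of Henle cells with 241 (1.5%) and podocytes, the filter cells of the glomerulus, with 233 (1.45%). Each of the other 9 types held 135 cells or fewer, among them 48 mesangial cells. The Kap transcript, which proximal tubule cells make under androgens, was detected in 91.0% of proximal tubule cells, but also in 83.1% of endothelial cells, 87.8% of distal tubule cells and 90.6% of podocytes. Median depths in the first 3 of these were 2169, 2025 and 2870.5 UMIs. Kap in endothelial cells, distal tubule cells and podocytes was read as free RNA, not as expression.

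The first comparison asked which transcripts differ in diabetes, between diabetic and control mice given vehicle. In proximal tubule cells of diabetic mice, Bhmt, the enzyme that remethylates homocysteine with betaine, rose 5.48-fold, from 8.87 ± 3.31 CPM (SD, n = 5) to 53.5 ± 9.91 (n = 4). Retreg1, a receptor for the autophagy of endoplasmic reticulum, rose from 156 ± 11.2 to 353 ± 33.4 CPM, and Pnpla2, the lipase that opens the breakdown of stored triglyceride, from 37.4 ± 4.88 to 84.4 ± 17.7 CPM. Cpe, a carboxypeptidase that processes prohormones, fell from 66.7 ± 17.1 to 10.0 ± 1.71 CPM, and Il34, a cytokine that binds the CSF1 receptor of macrophages, from 16 ± 4.85 to 0.813 ± 0.414 CPM. C1qtnf3, a secreted protein of the C1q and TNF family, and Trabd2b, a metalloprotease that cleaves Wnt proteins, also fell. The log2 fold changes were 2.45 for Bhmt (SE 0.212, adjusted p = 3.72e-07), 1.18 for Retreg1 (SE 0.118, 1.69e-06) and 1.18 for Pnpla2 (SE 0.142, 3.34e-05). They were -2.69 for Cpe (SE 0.237, 3.72e-07), -4.42 for Il34 (SE 0.485, 7.24e-06), -1.88 for C1qtnf3 (SE 0.187, 1.69e-06) and -1.17 for Trabd2b (SE 0.141, 3.34e-05). Aldh1a1 and Aldh1a7, neighbouring aldehyde dehydrogenase genes on chromosome 19, rose by 2.05 and 2.01 (adjusted p = 9.25e-05 for both), but their sequences are nearly alike, so which of them the counts belong to is uncertain. The processed transcript AC158982.1 fell by 4.11 on the log2 scale (adjusted p = 8.33e-05; -4.99 without diabetic vehicle replicate 3). For every called gene named here, all 4 diabetic vehicle mice lay on the side of the fold from the control vehicle mean. On GRCm38, Bhmt lies on chromosome 13 from 93616675 to 93637961 (minus strand) and Retreg1 on chromosome 15 from 25843180 to 25973687 (plus). Pnpla2 lies on chromosome 7 from 141455198 to 141460743 (plus), Cpe on chromosome 8 from 64592542 to 64693054 (minus) and Il34 on chromosome 8 from 110741829 to 110805924 (minus).

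Across the 3 cell types, 582 of 18544 gene tests passed in diabetes, 286 higher and 296 lower (edgeR quasi-likelihood), and 2689 had an unadjusted p under 0.05. Proximal tubule cells held 505 of these calls (243 higher, 262 lower), endothelial cells 47 (30 higher, 17 lower) and distal tubule cells 30 (13 higher, 17 lower). DESeq2 called 685, of which 553 were shared. Within replicate numbers 1 and 2 alone 189 tests passed (146 shared) and within numbers 3 and above 171 (141 shared). All 56 named genes called in diabetes kept their direction within both sets of numbers, where 24 (early) and 26 (late) passed. They were chosen by their calls on these same mice, which by itself favours a kept direction. The 17 called gene lists, called on these same mice, had medians in the called direction within both sets, but their size could differ. In endothelial cells the NF-kB list had a median log2 fold change of 0.648 early and 0.092 late. In distal tubule cells gluconeogenesis and glucose transport had 0.697 and 0.22. The count was 279 without diabetic vehicle replicate 2, 329 without diabetic vehicle replicate 3 and 335 without control vehicle replicate 3, and 600 at most with any 1 mouse left out.

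Some metabolic genes of the proximal tubule rose in diabetes, and most members of their lists did not pass over all genes. Of 15 tested genes of gluconeogenesis and glucose transport, 5 rose over all genes and 10 passed when adjusted over the list alone (9 higher, 1 lower). They included the glucose transporter Slc2a2 (214 to 322 CPM, log2 0.59, adjusted p = 0.00464) and the fructose transporter Slc2a5 (log2 0.92, 0.00616). They also included the glucose-6-phosphate transporter Slc37a4 (228 to 344 CPM, log2 0.59, 0.00797) and the sugar transporter Slc5a10 (90.0 to 261 CPM, log2 1.52, 0.00868). Slc5a2, the main glucose transporter of the early proximal tubule, had a log2 fold change of 0.17 that did not pass (adjusted p = 0.857), and Txnip, a glucose-responsive inhibitor of thioredoxin, one of 1.37 that did not pass (adjusted p = 0.186). Of 26 fatty acid oxidation and PPAR-alpha target genes, 4 rose over all genes and 10 when adjusted over the list alone. Among them were Acaa2, which closes the beta-oxidation cycle (358 to 635 CPM, log2 0.83, adjusted p = 0.00528), Cyp4a14, a fatty acid hydroxylase (19.9 ± 17.1 to 244 ± 155 CPM, log2 3.54, 0.00572), and Hadha, a subunit of the mitochondrial trifunctional protein (log2 0.48, 0.0425). Control vehicle replicate 1 held 50.1 CPM of Cyp4a14, the others of its group 7.54 to 15.6 CPM, and without it the log2 fold change was 4.25. Of 48 nuclear genes of oxidative phosphorylation 3 rose, Ndufb9, Cox5b and Atp5o, by 0.47, 0.42 and 0.43 (4 when adjusted over the list alone). Atp5o is a symbol of 2 annotated genes. The lists passed camera upward, with adjusted p = 9.31e-05 for gluconeogenesis and glucose transport, 1.29e-06 for fatty acid oxidation and 1.06e-06 for oxidative phosphorylation. With an estimated correlation the adjusted p were 0.182, 0.382 and 0.490, so none of the 3 calls held. Ribosomal protein genes (adjusted p = 5e-08 by camera, 0.483 with an estimated correlation; 0 of 49 called, 0 when adjusted over the list alone) and mitochondrially encoded genes (0.0112 and 0.522; 0 of 10 called, 2 when adjusted over the list alone) also passed camera upward.

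Most heat shock genes and a few unfolded protein response genes of the proximal tubule fell in diabetes. All 12 tested heat shock genes had negative folds, 8 fell over all genes, and 12 when adjusted over the list alone. Dnaja1, a cochaperone of HSP70, fell from 649 to 289 CPM (log2 -1.17, adjusted p = 9.25e-05), and Hsp90ab1, a main cytosolic chaperone, from 2220 to 1387 CPM (log2 -0.68, 0.00898). Dnajb1, another cochaperone, fell by 1.15 on the log2 scale (0.00422). Hspa1a, the inducible HSP70, fell from 17.7 to 0.663 CPM (log2 -4.74, 0.0102, and -5.66 without diabetic vehicle replicate 1), but its sequence is nearly that of Hspa1b (log2 -3.95, 0.0135), so which of the pair the counts belong to is uncertain. Of 18 unfolded protein response genes 3 fell over all genes, and 12 passed when adjusted over the list alone (11 lower, 1 higher). The unfolded protein genes were Pdia3 and Pdia4, which form disulfide bonds in the endoplasmic reticulum, and Edem1, which routes misfolded glycoproteins to degradation (log2 -0.75, -0.82 and -0.72, adjusted p = 0.0367, 0.0359 and 0.0359). Camera gave adjusted p = 1.45e-11 for heat shock and 2.11e-06 for the unfolded protein response, and 0.182 and 0.382 with an estimated correlation. The summed heat shock level was 8466 ± 723 CPM in control vehicle and 5061 ± 697 CPM in diabetic vehicle mice (exact permutation p = 0.0079, adjusted p = 0.0758; differences of -3965 and -2871 CPM within the early and late numbers).

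Of 15 androgen-regulated genes of the proximal tubule, 7 fell over all genes and 11 passed when adjusted over the list alone (10 lower, 1 higher). Slco1a1, an organic anion transporter, fell from 234 to 31.4 CPM (log2 -2.89, adjusted p = 0.0124), and Acsm3, an acyl-CoA synthetase, from 311 to 62.5 CPM (log2 -2.32, 0.0289). Odc1, the first enzyme of polyamine synthesis, fell by 1.39 on the log2 scale (0.0177), and Slc22a28, an organic anion transporter, by 1.25 (0.0194). Kap itself fell from 24640 to 5518 CPM (log2 -2.16, adjusted p = 0.0402). The list passed camera with adjusted p = 1.06e-07, and 0.300 with an estimated correlation. The Kap ratio of diabetic to control vehicle was 0.220 in proximal tubule cells (exact permutation p = 0.0079, adjusted p = 0.0758), 0.245 in barcodes without annotation (p = 0.0079, adjusted p = 0.0758), 0.213 in endothelial cells (p = 0.0159, adjusted p = 0.109) and 0.206 in distal tubule cells (p = 0.0397, adjusted p = 0.212). The differences within the early and late numbers were -22750 and -15839 CPM in proximal tubule cells, -17490 and -12463 CPM in barcodes without annotation, -4390 and -2390 CPM in endothelial cells and -4693 and -1720 CPM in distal tubule cells. Diabetic vehicle replicate 2 stood apart from its group, at 675 CPM in proximal tubule cells against 6002 to 7843 CPM, at 586 against 5023 to 7302 CPM in barcodes without annotation and at 154 against 738 to 1576 CPM in endothelial cells. Without it the 3 ratios were 0.285, 0.316 and 0.271. The distal tubule ratio was 0.110 without diabetic vehicle replicate 1, which stood at 1784 CPM against 129 to 718 CPM in the others of its group. As single genes, Kap in endothelial and distal tubule cells did not pass (log2 -2.19 and -2.28, adjusted p = 0.156 and 0.163). Single-gene calls that ended when 1 mouse was left out were those of Kap, Acsm3, Odc1, Slc22a28, Hsp90ab1, Hspa1a, Hadha, Cox5b, Atp5o, Pdia3, Pdia4 and Edem1.

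**Figure D1:**
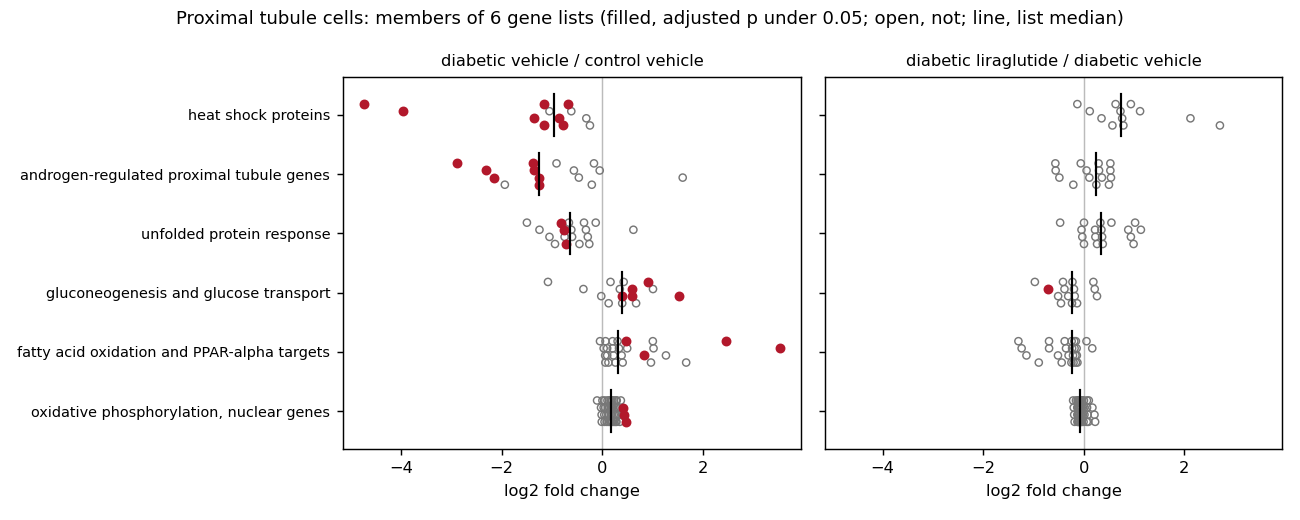
Members of 6 gene lists in proximal tubule cells, with the log2 fold change of diabetic over control vehicle (left) and of diabetic liraglutide over diabetic vehicle (right) on the x axis; filled points passed the test over all genes, open points did not, and the line is the list median. In diabetes all 12 heat shock genes lie below 0 and 25 of 26 fatty acid oxidation genes above it.

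Of the other lists in proximal tubule cells in diabetes, the red blood cell list passed camera downward (adjusted p = 0.00306, and 0.483 with an estimated correlation; 1 of 7 called, 6 when adjusted over the list alone). Hemoglobin transcripts stood at 2025 ± 2799 CPM in control vehicle and 129 ± 93.5 CPM in diabetic vehicle mice (exact permutation p = 0.214). Control vehicle replicate 2 stood at 6755 CPM, and the others of its group at 8.22 to 2387 CPM, with a mean of 842 CPM without that mouse. The differences were -4375 CPM within the early and -264 CPM within the late numbers. The remaining 18 lists did not pass camera. Their adjusted p were 0.0651 for cAMP and CREB targets, 0.0651 for complement and coagulation, 0.163 for oxidative stress and NRF2 targets, and 0.287 for NF-kB targets, for the cell cycle and for cholesterol synthesis. They were 0.309 for glycolysis and hypoxia, 0.513 for the podocyte list, and 0.594 for the proximal tubule free RNA list. They were 0.612 for immediate early genes and for tubular injury, 0.729 for extracellular matrix, and 0.892 for the renin-angiotensin system. Their test and median differed in sign for interferon (adjusted p = 0.513), RAGE and its ligands (0.595), endothelial activation (0.64), MHC class II (0.69) and MHC class I (0.992). Ager, Glp1r, Havcr1, Vcam1, Ccl2 and Fos did not pass the filter on low counts in any tested type. The median mitochondrial share of UMIs per mouse was 7.65 ± 0.873% in control vehicle and 11.3 ± 0.604% in diabetic vehicle mice (exact permutation p = 0.0079, adjusted p = 0.0758). It was higher by 3.21 points within numbers 1 and 2 and by 3.87 points within numbers 3 and above. This difference lay between the same groups of mice as the gene differences above. Whether the share varied with those genes from mouse to mouse was not tested.

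Endothelial cells of diabetic mice held more Fabp4, a fatty acid binding protein, which rose from 225 ± 43.5 to 1525 ± 560 CPM, and more Serpine2, an inhibitor of thrombin and plasmin, which rose from 91.7 ± 16.1 to 356 ± 79.1 CPM. Plat, the tissue plasminogen activator, rose from 5790 to 10900 CPM, and Igfbp5, which binds insulin-like growth factors, fell from 5737 ± 823 to 2591 ± 1127 CPM. The log2 fold changes were 2.71 for Fabp4 (SE 0.321, adjusted p = 1.58e-04), 1.92 for Serpine2 (SE 0.239, 6.48e-06), 0.92 for Plat (0.00107) and -1.15 for Igfbp5 (SE 0.198, 0.00114). The transcription factor Klf9 and Serinc3 rose (log2 1.08 and 0.80, adjusted p = 0.00261 and 0.00361), while the matrix protein Olfml2b, the receptor Ccrl2 and the tubulin Tuba1b fell (log2 -1.67, -0.96 and -0.78, adjusted p = 0.00219, 0.0128 and 0.0155). Amacr, an enzyme of branched fatty acid breakdown, fell from 471 to 224 CPM in proximal tubule cells (adjusted p = 0.00114). In endothelial cells it was counted at 105 and 18.3 CPM (adjusted p = 0.0121). Kap stood there at 0.167 of its proximal tubule level in control vehicle mice, so the endothelial Amacr counts were read as free RNA in part. On GRCm38, Fabp4 lies on chromosome 3 from 10204088 to 10208576 (minus strand), Serpine2 on chromosome 1 from 79794197 to 79861180 (minus) and Igfbp5 on chromosome 1 from 72857932 to 72874884 (minus).

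Heat shock genes were lower in endothelial cells too, by camera (adjusted p = 4.23e-09, and 0.182 with an estimated correlation), with 0 of 13 called over all genes and 7 lower when adjusted over the list alone. Their summed level was 8137 ± 1090 CPM in control vehicle and 4402 ± 711 CPM in diabetic vehicle mice (exact permutation p = 0.0159, adjusted p = 0.109; differences of -4002 and -3603 CPM within the early and late numbers). The unfolded protein response list passed downward (adjusted p = 0.00232, and 0.382 with an estimated correlation; 0 of 16 called, 1 when adjusted over the list alone). NF-kB targets passed upward (0.0219, and 0.300 with an estimated correlation), with 1 of 9 called, the NF-kB inhibitor Nfkbia (794 to 1457 CPM, log2 0.81, adjusted p = 0.0361), and 2 when adjusted over the list alone. The list median was 0.648 within the early and 0.092 within the late numbers. Icam1, an adhesion molecule for leukocytes, had a log2 fold change of 0.83 that did not pass (adjusted p = 0.129). Endothelial activation passed upward (0.0219, and 0.382 with an estimated correlation), with 2 of 22 called, Lrg1, a modulator of vessel growth (50.3 to 134 CPM, log2 1.57, adjusted p = 0.0226), and the surface antigen Ly6c1 (log2 0.65, 0.0355), and 7 when adjusted over the list alone. The calls of Amacr, Ccrl2, Tuba1b, Nfkbia, Lrg1 and Ly6c1 ended when p-values were adjusted within endothelial cells alone, which gave 9 calls. Those of Tuba1b, Nfkbia, Lrg1 and Ly6c1 also ended when 1 mouse was left out, and Lrg1 had a log2 fold change of 0.94 without diabetic vehicle replicate 2 (adjusted p = 0.39).

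**Figure D2:**
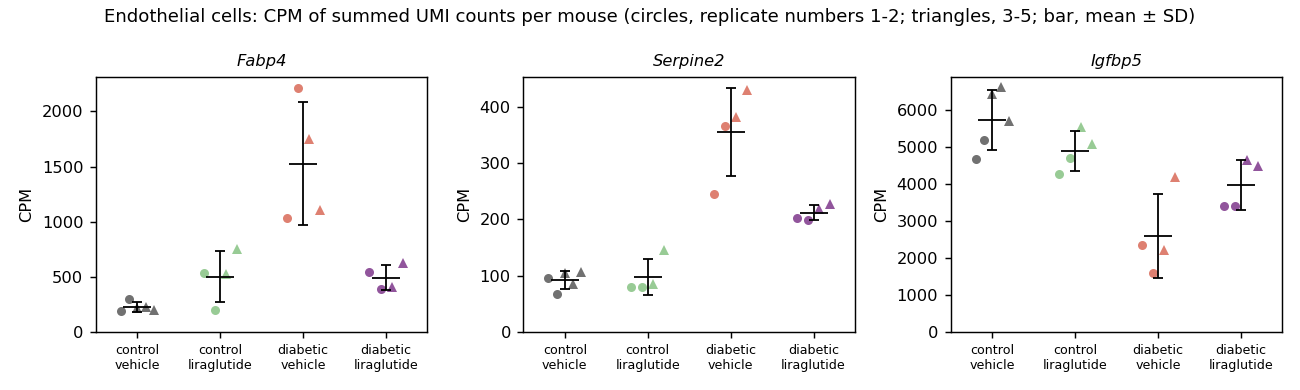
CPM of Fabp4, Serpine2 and Igfbp5 in endothelial cells of each mouse by group (circles, replicate numbers 1 and 2; triangles, 3 and above; bars, mean ± SD; y axes start at 0). Fabp4 averaged 225 CPM in control vehicle, 501 in control liraglutide, 1525 in diabetic vehicle and 491 in diabetic liraglutide mice.

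In distal tubule cells of diabetic mice, the histone gene H3f3b rose from 291 to 569 CPM (log2 0.94, SE 0.172, adjusted p = 0.00123), and Fth1, the ferritin heavy chain that stores iron, from 8372 to 11810 CPM (log2 0.50, SE 0.114, 0.00933). Acss1, a mitochondrial acetyl-CoA synthetase, the signalling regulator Rgs2 and the lipid carrier Apoe rose by 0.69, 2.05 and 1.51 (adjusted p = 0.0122, 0.011 and 0.0126). Lpl, the lipoprotein lipase, fell from 915 to 403 CPM (log2 -1.19, adjusted p = 0.0177), and Kitl, the ligand of KIT, the transcription factor Sox4 and the chromatin remodeller Chd3 fell by 1.29, 1.22 and 1.00 (0.0187, 0.0117 and 0.0219). Slc7a13, an amino acid transporter of the proximal tubule, fell from 842 to 136 CPM in proximal tubule cells (adjusted p = 0.0352). In distal tubule cells it was counted at 108 and 7.18 CPM (adjusted p = 0.00609). The control level there lay below 0.149 of the proximal tubule level, the ratio of Kap, so it was read as free RNA and not as a change of distal tubule cells. By camera, fatty acid oxidation (adjusted p = 6.33e-04; 1 of 18 called, 1 when adjusted over the list alone), gluconeogenesis and glucose transport (0.00698; 0 of 7, 0 when adjusted over the list alone) and ribosomal protein genes (3.47e-04; 0 of 49, 0 when adjusted over the list alone) were higher. Heat shock was lower (0.00186; 1 of 10, 1 when adjusted over the list alone). With an estimated correlation the adjusted p were 0.182, 0.483, 0.522 and 0.382. The summed heat shock level was 5604 ± 592 CPM in control vehicle and 4311 ± 235 CPM in diabetic vehicle mice (exact permutation p = 0.0238, adjusted p = 0.143; differences of -1280 and -1291 CPM within the early and late numbers). Of the 10 distal tubule genes named, H3f3b alone passed when p-values were adjusted within this type (1 call in all). The calls of Rgs2, Apoe, Lpl, Kitl, Sox4, Chd3 and Slc7a13 ended when 1 mouse was left out, in each case without diabetic vehicle replicate 2 or 3. Rgs2 was 99.1 CPM in control vehicle replicate 5 and 10.5 to 32.0 CPM in the others of its group, and without that mouse its log2 fold change was 2.70. Slc7a13 had -4.54 without diabetic vehicle replicate 1.

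For the shares of the 14 cell types the permutation tests could not call a single type. With the smallest p possible a lone type has an adjusted p of 0.111 for 5 against 4 mice and 0.4 for 4 against 4, and 3 or 8 types would have to reach it together. The edgeR test on cells per type, which has no such bound, made no call (2 types in diabetes with an unadjusted p under 0.05, smallest adjusted p = 0.322, and 0 in each liraglutide comparison). The smallest permutation p in diabetes belonged to loop of Henle cells, at 1.90 ± 0.465% of cells in control vehicle and 0.811 ± 0.339% in diabetic vehicle mice (exact permutation p = 0.0159, adjusted p = 0.222; differences of -0.987 and -1.11 points within the early and late numbers). Podocytes stood at 1.75 ± 0.856% and 0.876 ± 0.348% (exact permutation p = 0.119, adjusted p = 0.556).

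The next comparison asked what liraglutide does in diabetic mice. In the proximal tubule, Retreg1, the receptor for autophagy of the endoplasmic reticulum, fell from 353 ± 33.4 to 188 ± 12.3 CPM (SD, n = 4 in each group), and Pnpla2, the triglyceride lipase, from 84.4 ± 17.7 to 40.1 ± 4.57 CPM, near their control vehicle means of 156 and 37.4 CPM. Slc37a4, the glucose-6-phosphate transporter, fell from 344 ± 46.7 to 210 ± 15.4 CPM, against 228 CPM in control vehicle mice. Itgb6, an integrin subunit of epithelial cells, rose from 132 ± 25.0 to 316 ± 63.5 CPM, above its control vehicle mean of 164 CPM. Nt5e, the enzyme that forms adenosine outside cells, rose from 11.6 ± 3.19 to 41.9 ± 15.7 CPM, having fallen in diabetes from 28.5 CPM (log2 -1.28, adjusted p = 0.00818). The log2 fold changes were 1.28 for Itgb6 (SE 0.171, adjusted p = 0.00147) and 1.85 for Nt5e (SE 0.276, 0.0039). They were -0.92 for Retreg1 (SE 0.126, 0.00147), -1.10 for Pnpla2 (SE 0.155, 0.00147) and -0.72 for Slc37a4 (SE 0.133, 0.0349). Each was shown by 4 of 4 diabetic liraglutide mice against the diabetic vehicle mean. The cation channel Trpv4 rose (log2 0.74, SE 0.134, adjusted p = 0.0288), and Fmo2, a flavin monooxygenase, and Marc2, a mitochondrial reductase, fell (log2 -0.65 and -0.70, adjusted p = 0.0221 for both). Dcaf8, a substrate receptor of ubiquitin ligases that was chosen after its values were seen, fell from 239 to 161 CPM (log2 -0.58, adjusted p = 0.0373).

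These 9 genes, 3 higher and 6 lower, were the calls among 18544 tests (edgeR quasi-likelihood), where 1598 had an unadjusted p under 0.05, and all were in proximal tubule cells. The count was 0 in endothelial cells (264 unadjusted) and 0 in distal tubule cells (205 unadjusted). DESeq2 called 37 in all, including the 9. Txnip, G6pc (the last enzyme of gluconeogenesis), Cpt1a (the gate of mitochondrial fatty acid import), Ddit3 (a stress transcription factor whose symbol matches 2 annotated genes), Slc5a2 and Kap had log2 fold changes of -1.09, -0.97, -0.51, 0.99, 0.22 and 0.53 in proximal tubule cells, and none passed (adjusted p = 0.595, 0.373, 0.131, 0.102, 0.902 and 0.86). The count was 0 within replicate numbers 1 and 2 alone, 26 within numbers 3 and above (4 shared), 142 with no filter on low counts and 2 in cells of 6 to 12% mitochondrial UMIs. With 1 mouse left out it was 4 without diabetic liraglutide replicate 4 or diabetic vehicle replicate 3, 5 without diabetic vehicle replicate 2, 25 without diabetic liraglutide replicate 1 and 31 without diabetic vehicle replicate 1. Itgb6, Nt5e, Retreg1 and Pnpla2 kept their calls with each mouse left out, and Slc37a4, Trpv4, Fmo2 and Marc2 did not. The 8 genes other than Dcaf8 kept their direction within both sets of numbers, where 4 passed in the late and none in the early set. Being called on these same mice by itself favours a kept direction. In the late set liraglutide cannot be told apart from the serial order of the diabetic mice.

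**Figure D3:**
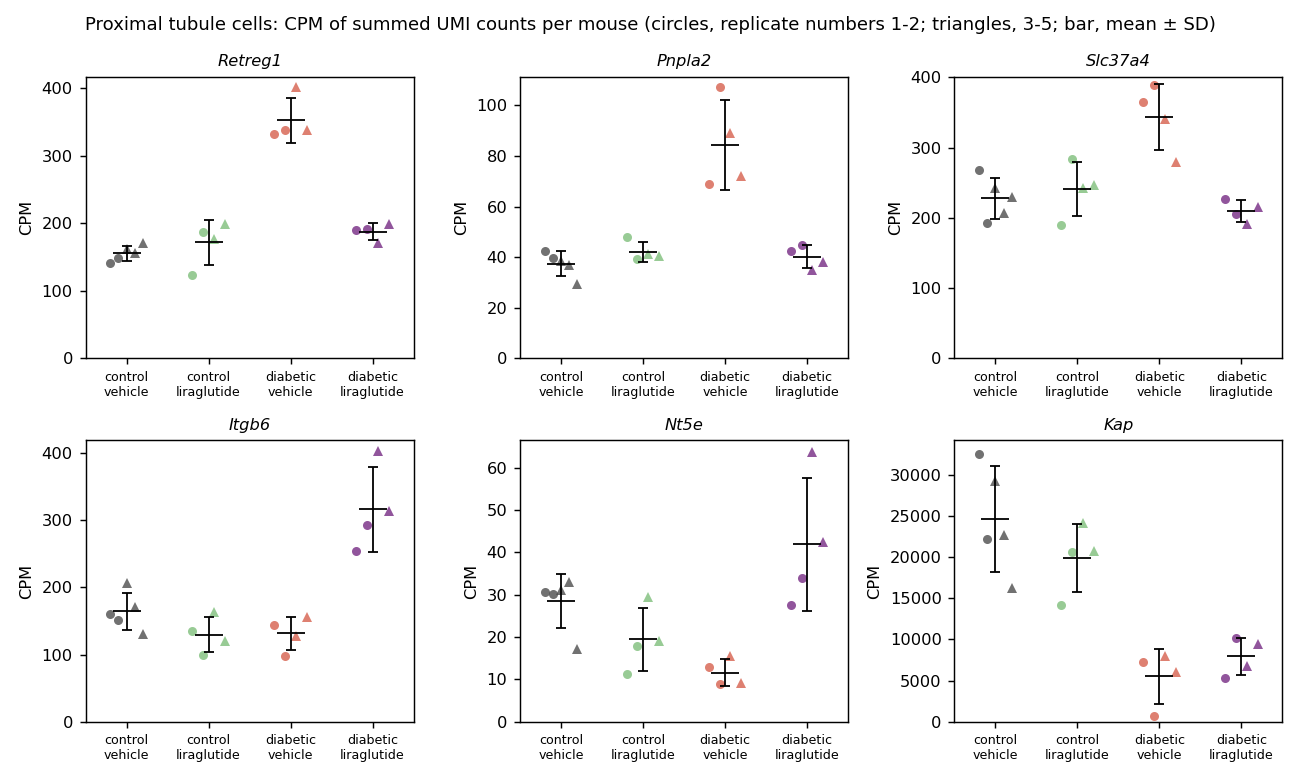
CPM of 6 genes in proximal tubule cells of each mouse by group (circles, replicate numbers 1 and 2; triangles, 3 and above; bars, mean ± SD; y axes start at 0). Retreg1 averaged 353 CPM in diabetic vehicle and 188 in diabetic liraglutide mice, and Itgb6 132 and 316.

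Several gene lists passed camera with liraglutide in diabetic mice in the direction opposite to diabetes. Both comparisons share the diabetic vehicle mice, which by itself favours opposite directions, and most members of these lists did not pass. Heat shock genes were higher by camera in proximal tubule cells (adjusted p = 3.88e-07; 0 of 12 called, 7 when adjusted over the list alone), endothelial cells (3.88e-07; 0 of 13, 4 when adjusted over the list alone) and distal tubule cells (0.0124; 0 of 10, 1 when adjusted over the list alone). With an estimated correlation the adjusted p were 0.343, 0.343 and 0.684. Hsph1, a partner of HSP70, was 36.2 CPM in diabetic vehicle and 148 CPM in diabetic liraglutide endothelial cells, which did not pass on its own (log2 1.88, adjusted p = 0.196; 3.20 and 0.0143 without diabetic vehicle replicate 1). The summed heat shock level in proximal tubule cells was 5061 ± 697 CPM in diabetic vehicle and 7115 ± 1637 CPM in diabetic liraglutide mice (exact permutation p = 0.0571, adjusted p = 0.274), with differences of 1151 CPM within the early and 2957 CPM within the late numbers. In endothelial cells it was 4402 ± 711 and 7718 ± 3273 CPM (exact permutation p = 0.0857, adjusted p = 0.374), with differences of 360.0 CPM within the early and 6273 CPM within the late numbers. In distal tubule cells it was 4311 ± 235 and 5963 ± 2111 CPM (exact permutation p = 0.314, adjusted p = 0.656), with differences of -38.5 CPM within the early and 3342 CPM within the late numbers, so the rise did not hold within the early numbers there.

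**Figure D4:**
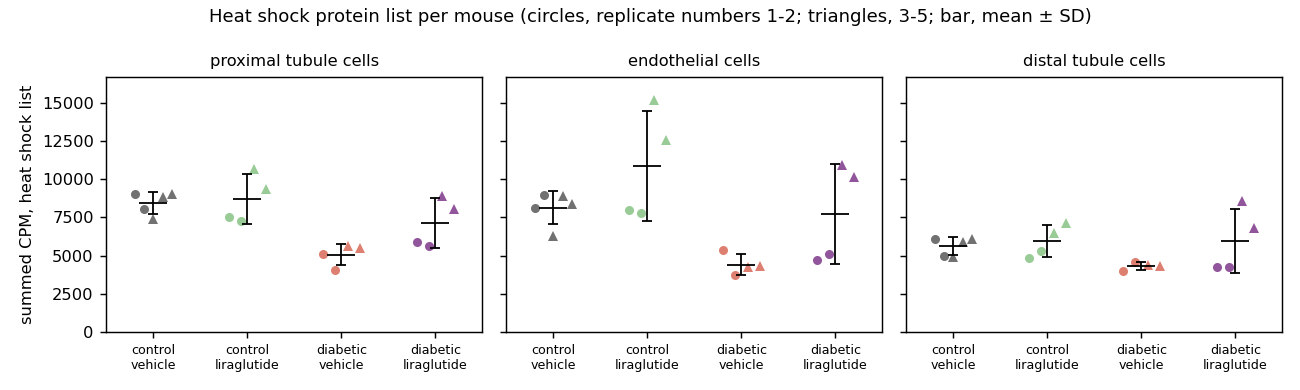
Summed CPM of the heat shock list per mouse by group in 3 cell types (circles, replicate numbers 1 and 2; triangles, 3 and above; bars, mean ± SD; y axis starts at 0). In proximal tubule cells the means were 8466 CPM in control vehicle, 8717 in control liraglutide, 5061 in diabetic vehicle and 7115 in diabetic liraglutide mice.

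Fatty acid oxidation genes were lower with liraglutide in proximal tubule cells (adjusted p = 1.5e-04 by camera; 0 of 26 called, 1 when adjusted over the list alone) and distal tubule cells (0.0262; 0 of 18, 0 when adjusted over the list alone), as were gluconeogenesis and glucose transport genes in proximal tubule cells (0.00676; Slc37a4 alone of 15 called, 1 when adjusted over the list alone). With an estimated correlation the adjusted p were 0.729, 0.343 and 0.343. The unfolded protein response was higher in proximal tubule cells (0.0203; 0 of 18 called, 1 when adjusted over the list alone) and endothelial cells (0.0426; 0 of 16, 0 when adjusted over the list alone), and the adjusted p with an estimated correlation were 0.831 and 0.729. MHC class I genes, which present antigen, were lower in proximal tubule cells (0.0213; 0 of 10, 0 when adjusted over the list alone) and endothelial cells (0.0203; 0 of 10, 0 when adjusted over the list alone), with adjusted p of 0.585 and 0.684 with an estimated correlation. H2-Q7 of this list had a log2 fold change of -1.93 in endothelial cells that did not pass (adjusted p = 0.436; -0.32 without diabetic vehicle replicate 2). In distal tubule cells the podocyte list (0 of 5 called, 0 when adjusted over the list alone) and cholesterol synthesis (0 of 6, 1 when adjusted over the list alone; Hmgcs1, an early enzyme of the pathway, log2 0.81, adjusted p = 0.149) were higher, both with adjusted p = 0.0306, and 0.343 with an estimated correlation. In all, 12 of 64 list tests passed camera with the preset correlation, against 17 of 64 in diabetes. Of the 12, called on these same mice, 9 had medians in the called direction within both sets of numbers. The others were heat shock in distal tubule cells (log2 -0.163 early, 0.888 late), the unfolded protein response in proximal tubule cells (-0.009 early, 0.438 late) and MHC class I in endothelial cells (-0.727 early, 0.021 late). Among the 9, some early medians were small beside the late ones. They were 0.004 and 0.489 for the distal tubule podocyte list. In endothelial cells they were 0.041 and 0.305 for the unfolded protein response and 0.101 and 1.323 for heat shock. The median mitochondrial share was 10.8 ± 2.67% in diabetic liraglutide against 11.3 ± 0.604% in diabetic vehicle mice (exact permutation p = 0.714), with differences of 1.73 points within the early and -2.68 points within the late numbers.

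Across all tested genes, the folds of liraglutide in diabetic mice were negatively related to those of diabetes, in part because both share the diabetic vehicle mice. In proximal tubule cells the covariance over 10541 genes was -0.0698, against -0.0403 (SD 0.0013) simulated with no effect for the shared diabetic vehicle mice. The correlation across genes was -0.51, against -0.508 simulated, so it showed no excess. With different diabetic vehicle mice in the 2 comparisons the covariance was -0.0313 (SD 0.0155 over 6 orderings, from -0.0479 to -0.0129) and the mean correlation -0.185. In endothelial cells the covariances were -0.0878 and -0.0666 simulated, and -0.0213 (SD 0.0123) with different mice, and the correlation -0.593 against -0.545 simulated. In distal tubule cells they were -0.0545 and -0.0466, and -0.0092 (SD 0.0136), which is within the spread of the orderings, and the correlation was -0.483 against -0.470 simulated. Of the proximal tubule calls, 4 genes were higher in diabetes and lower with liraglutide, where 0.136 would be shared by independent lists, 1 was lower and then higher (0.0734), and 0 were called in the same direction. Both comparisons share the diabetic vehicle mice, which raises this overlap.

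The interaction asked if the liraglutide difference depends on diabetes. The test called Itgb6, Nt5e, Retreg1 and Pnpla2 in proximal tubule cells, the 4 calls among 18544 tests (1158 with an unadjusted p under 0.05, and 13 calls by DESeq2). Splits within the early and within the late mice did not exclude chance for this count. Itgb6 and Nt5e differed by 1.63 (SE 0.238, adjusted p = 0.00943) and 2.39 (SE 0.378, 0.0138), and Retreg1 and Pnpla2 by -1.07 (SE 0.174, 0.0138) and -1.25 (SE 0.217, 0.0288). In control mice the liraglutide folds of Itgb6, Nt5e and Retreg1 were -0.35, -0.54 and 0.16 and did not pass (adjusted p = 1 for each). The count was 0 within replicate numbers 1 and 2 alone, 56 with no filter on low counts, 1 in cells of 6 to 12% mitochondrial UMIs, 1 without control liraglutide replicate 4, 2 without diabetic vehicle replicate 2 or 3, and 7 without diabetic vehicle replicate 4.

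The last comparison asked what liraglutide does in control mice, in 5 cell types. No single gene passed there: podocytes, loop of Henle cells and the 3 types above gave 0 calls of 22538 tests (edgeR quasi-likelihood), with 855 at an unadjusted p under 0.05 and 0 calls by DESeq2. The smallest p belonged to Ctgf, a matrix-associated growth factor that stood at 226 CPM in control vehicle (4 mice) and 747 CPM in control liraglutide podocytes (3 mice). Next came the netrin receptor Unc5c in podocytes, Ccdc85c in proximal tubule cells, the stress gene Ier3 in endothelial cells and Herpud1, which acts in degradation of endoplasmic reticulum proteins, in loop of Henle cells. Their log2 fold changes were 1.76, -1.88, 0.77, 1.59 and 1.24, with adjusted p = 0.627 for each. Ren1, the renin gene, stood at 2.08 and 11.7 CPM in proximal tubule cells (log2 2.78, adjusted p = 1, and 1.84 without control liraglutide replicate 2). In cells that the authors named juxtaglomerular it stood at 9769 CPM over all mice. The low proximal tubule counts were not told apart from free RNA. The count of calls was 11 with no filter on low counts, 2 with the proximal tubule free RNA covariate, 1 within the early numbers, 5 within the late numbers, and 4 at most with 1 mouse left out (control liraglutide replicate 2).

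Of 92 list tests in control mice, 9 passed camera, and all had an adjusted p of 0.976 with an estimated correlation. Ribosomal protein genes were higher and androgen-regulated genes lower in proximal tubule cells (adjusted p = 7.69e-04 and 0.0213). Heat shock genes were higher in endothelial cells and podocytes (0.0229 and 0.0317), and gluconeogenesis and glucose transport genes were higher in distal tubule cells (0.0317). Oxidative phosphorylation genes were higher in endothelial cells (0.0229) and lower in loop of Henle cells (0.0229) and distal tubule cells (0.0294). The proximal tubule free RNA list was higher in loop of Henle cells (0.00216). The endothelial heat shock rise did not hold within the early numbers, where the list median was -0.014 against 0.797 in the late, with differences of the summed level of -667 and 6017 CPM. The median of the ribosomal list was 0.192 in the early and -0.008 in the late numbers. Another 4 lists, called on these same mice, had medians in the called direction within both sets. The 3 in loop of Henle cells and podocytes held too few mice for values in both sets. In these 9 tests 0 genes were called over all genes, and when adjusted over the list alone 1 gene of the free RNA list and 0 of the others passed. Mesangial cells had the smallest p of the cell type shares, at 0.242% in control vehicle and 0.778% in control liraglutide mice (exact permutation p = 0.0635, adjusted p = 0.583). In diabetic mice the smallest p belonged to endothelial cells, at 8.33 ± 4.48% with vehicle and 12.2 ± 1.95% with liraglutide (exact permutation p = 0.143, adjusted p = 0.836).

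The authors' deposited table compares cells, not mice, and its calls were counted at its own adjusted p under 0.05. It draws on the same mice as the tests here, which by itself favours shared directions. Shared calls and directions are therefore not independent support. In diabetes it holds 922 calls in proximal tubule cells (502 higher, 420 lower), 115 in endothelial cells and 30 in distal tubule cells. Of these, 313, 27 and 7 were also called here, and all 922 in proximal tubule cells had the same direction here. The authors list 4468 genes in proximal tubule cells, where 10715 were tested here. Of the 505 proximal tubule calls made here, 322 are among the listed genes. In endothelial cells all 47 calls are listed, and in distal tubule cells 29 of 30. For liraglutide in diabetic mice it holds 490 calls in proximal tubule cells, among them all 9 called here, and 488 of the 490 had the same direction here. It holds 62 calls in endothelial cells and 5 in distal tubule cells for that comparison. For liraglutide in control mice it holds 282 in proximal tubule cells, 27 in endothelial cells, 3 in distal tubule cells and 2 in podocytes, where 0 were called here (edgeR quasi-likelihood; 855 at an unadjusted p under 0.05, and 0 by DESeq2).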

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

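The tests of isolation stress through immediate early genes and of the early and late numbers for liraglutide, the cells of 6 to 12% mitochondrial UMIs, the cells of 1500 to 3000 UMIs, the splits that divide early and late mice evenly and the fits within each set of numbers were chosen after results were seen.

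The 4 genes called in the interaction stand out because the dependence of the liraglutide difference on diabetes was itself tested. The proximal tubule liraglutide fold in diabetic mice exceeded that in control mice by 1.63 for Itgb6 and 2.39 for Nt5e on the log2 scale, and the difference was -1.07 for Retreg1 and -1.25 for Pnpla2. The real grouping gave 4 interaction calls, and 2 of 60 splits over all mice gave as many. Those splits ignore the early and late numbers. They also shuffle all 4 groups, so differences between control and diabetic mice enter the spread within groups. For these reasons they were not read as excluding chance. Among 40 splits within the early and within the late mice, 2 gave as many (highest other 26). There too chance could not be excluded. Within numbers 1 and 2 alone the count was 0 (edgeR). Itgb6, Nt5e and Retreg1, called on these same mice, kept their direction within both sets of numbers, which the calls by themselves favour. In either set 0 of the 3 passed. With each mouse left out 1 of these 3 kept its call. The highest of the splits over all mice gave 363 calls, many times the real count, in the split of the 60 that followed the early and late numbers most closely, which points to that structure of the samples.

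By camera, heat shock transcripts were lower in diabetes and higher with liraglutide in diabetic mice in 3 cell types, but with an estimated correlation no call held (adjusted p = 0.182, 0.182 and 0.382 in proximal tubule, endothelial and distal tubule cells in diabetes, and 0.343, 0.343 and 0.684 with liraglutide), and the summed levels with liraglutide did not pass (exact permutation p = 0.0571, 0.0857 and 0.314). Free RNA from proximal tubule cells is argued against as the main source of these transcripts in the other types. Their level in control vehicle distal tubule cells was 0.662 of that in proximal tubule cells (0.961 in endothelial cells), where free RNA gave Kap ratios of 0.149 and 0.167. These ratios concern the level and not how much of the difference between groups free RNA carried. In diabetes the summed level differed by -3405 CPM in proximal tubule, -3735 CPM in endothelial and -1293 CPM in distal tubule cells. A part carried by free RNA therefore stays open, above all in distal tubule cells. The early and late numbers are argued against as the whole cause in diabetes, where the proximal tubule list median was -0.712 in 1 set and -1.18 in the other, and for liraglutide in proximal tubule cells, where it was 0.413 (early) and 0.905 (late). For liraglutide in distal tubule and endothelial cells the medians were -0.163 and 0.101 in the early against 0.888 and 1.32 in the late numbers, so the difference there followed the late mice. Among those mice liraglutide and the serial order cannot be told apart. Stress of cell isolation stays open, since the immediate early list had a median of 0.183 in diabetes and members in both directions. The SE of that list was 0.214, taken over its member genes and not over mice. A response of the cells to diabetes and to liraglutide stays open as well, and it cannot be told apart from isolation stress.

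The proximal tubule calls in diabetes stood beside a higher mitochondrial share, 8.14% in control and 11.9% in diabetic vehicle as the median over proximal tubule cells. The mitochondrial share alone is argued against as their whole cause. In cells of 6 to 12% mitochondrial UMIs (medians 8.69% and 8.99%), 450 of the 451 called genes tested there kept their sign. Their folds had a slope of 1.049 against those in all cells (SE 0.01 over genes, which are not independent, and not over mice). Median depth in these cells was 1975.5 UMIs in control and 2716 in diabetic vehicle mice, and no cells matched on both were tested. The genes were called in the same mice and partly the same cells, which favours a slope near 1. In cells of 1500 to 3000 UMIs the slope was 0.994 (SE 0.01, again over genes) for 381 genes, all 381 of the same sign. Median depth was 2138.5 and 2266 UMIs in all cells of control and diabetic vehicle mice, and 2142 and 2146 in this band. The band removed little difference in depth, so its slope decides little about depth. The mitochondrial share in the band stayed at 8.11% and 11.9%. The real grouping gave 582 calls, the highest of the other splits 198, and 1 of 100 splits, the real one, as many, so chance can be excluded for the count. A response of the tubule to diabetes stays as a hypothesis, found and tested on the same mice.

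The folds of liraglutide in diabetic mice had a negative covariance with those of diabetes, while their proximal tubule correlation of -0.51 did not exceed the simulated -0.508. The shared diabetic vehicle mice are argued against as the whole cause, since the proximal tubule covariance with different mice in each comparison was -0.0313 (SD 0.0155). A part resting on diabetic vehicle replicate 2 stays open, since the covariance beyond the simulated value was -0.0295 with all mice and -0.013 without that mouse. Chance could not be excluded, since 5 of 35 splits of the 8 diabetic mice gave a covariance as low as the real -0.0698, the lowest being -0.0907. A return toward the control state under liraglutide stays open as well.

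For the other counts, chance could not be excluded over all splits drawn. Liraglutide in diabetic mice gave 9 gene calls, and 2 of 35 splits gave as many, the highest other being 66 in the split that put the early mice on 1 side, which points to a structure of the samples. Among the 18 splits that divide the early and late mice evenly, too few for a share under 0.05, the real grouping gave 9 and the highest other 5. Liraglutide in control mice gave 0 gene calls, which any split must reach (100 of 100, with a highest of 26), so that count decides nothing. List calls numbered 17 in diabetes (17 of 100 splits gave as many, highest other 29), 12 for liraglutide in diabetic mice (17 of 35, highest other 28) and 9 for liraglutide in control mice (74 of 100, highest other 38). Among the splits that divide the early and late mice evenly, 1 of 48, the real one, gave 17 list calls in diabetes (highest other 16). That margin is 1 call, the count was 16 without control vehicle replicate 3, and 0 of the calls held with an estimated correlation, so this does not exclude chance. In control mice 25 of 47 gave 9 or more list calls (highest other 19), so chance could not be excluded. The 18 such splits of the diabetic mice are too few for a share under 0.05 (12 list calls, highest other 13).

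Single mice that stood far from the others of their group were marked in 18 of 248 groups of values (7.3%), where chance marks about 1 in 20. Diabetic liraglutide replicate 3 had 1259 annotated cells, against 439 to 553 in its group. Hemoglobin transcripts in endothelial cells were 11217 CPM in control vehicle replicate 1, against at most 2338 CPM. The share of cells that the authors named juxtaglomerular was 0.188% (3 cells) in control vehicle replicate 3 and 0.069% (1 cell) in diabetic vehicle replicate 3, against 0% in the others of each group. Beside Ren1, the leading genes of this type held smooth muscle genes such as Acta2 and Myh11. Loop of Henle cells were 0% in diabetic liraglutide replicate 1, against 1.27 to 1.43%, and mesangial cells 0% in control vehicle replicate 1, against 0.285 to 0.313%. Neutrophils were 2.13% (23 cells) in diabetic vehicle replicate 2, against at most 0.069%. Principal cells were 0.654% (3 cells) in diabetic vehicle replicate 4, against 0.069 to 0.122% (1 cell in each). Shares that rest on so few cells can stand apart through 1 or 2 cells. In distal tubule cells, Lpl was 1337 CPM in control vehicle replicate 4 (others 767 to 905) and Rgs2 99.1 CPM in control vehicle replicate 5 (others 10.5 to 32.0). In endothelial cells, Ccrl2 was 460 CPM in control vehicle replicate 4 (others 239 to 291) and Fabp4 299 CPM in control vehicle replicate 2 (others 191 to 221). In proximal tubule cells of control vehicle mice, Cyp4a14 was 50.1 CPM (others 7.54 to 15.6) and Slc2a5 70.0 CPM (others 39.0 to 44.2) in replicate 1, Dnajb1 60.3 CPM (others 30.7 to 38.2) in replicate 2, and Nt5e 17.3 CPM (others 30.2 to 33.0) in replicate 5. In diabetic vehicle replicate 3, proximal tubule Cpe was 12.6 CPM (others 9.09 to 9.22) and Retreg1 403 CPM (others 332 to 338).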

How the results depend on the processing

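The early-late term, the fits within each set of replicate numbers, the mitochondrial band and the genes chosen in 1 pair of mice were added after the data were seen; the other settings were planned, and where a value moved the cause was not tested. The 582 gene calls of diabetes stayed within 1.5 times in 14 of 16 settings, and were 189 within numbers 1 and 2 (146 shared) and 171 within numbers 3 and above (141 shared), which hold fewer mice. With 1 mouse left out they ranged from 279 (diabetic vehicle replicate 2) to 600, with 329 without diabetic vehicle replicate 3 and 335 without control vehicle replicate 3.

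The 9 calls of liraglutide in diabetic mice became 142 with no filter on low counts, 14 with the 2 groups alone, 24 with the replicate block, 37 with DESeq2, 2 in the mitochondrial band, 26 with the early-late term, 25 with that term and the covariate, 0 within numbers 1 and 2 and 26 within numbers 3 and above. With 1 mouse left out they ranged from 4 (diabetic liraglutide replicate 4; also diabetic vehicle replicate 3, and 5 without diabetic vehicle replicate 2) to 31 (diabetic vehicle replicate 1; 25 without diabetic liraglutide replicate 1). The 0 calls of liraglutide in control mice (edgeR, 855 unadjusted, 0 by DESeq2) became 11 with no filter, 1 with the 2 groups alone, 3 with the block, 2 with the covariate, 2 with the early-late term, 5 with both, 1 and 5 within the early and late numbers, and 0 to 4 with 1 mouse left out (4 without control liraglutide replicate 2). The 4 interaction calls became 56 with no filter, 17 with the block, 13 with DESeq2, 1 in the mitochondrial band, 11 with the early-late term and covariate and 0 within numbers 1 and 2, and ranged from 1 (control liraglutide replicate 4) to 7 (diabetic vehicle replicate 4) with 1 mouse left out, with 2 without diabetic vehicle replicate 2 or 3. The replicate numbers do not all pair the mice: the deviations of equal numbers correlated above 0.1 in 19 of 24 pairs in proximal tubule cells, 20 of 24 in endothelial and 16 of 24 in distal tubule cells, and followed the early and late sets.

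The 17 list calls of diabetes became 27 with the covariate, 5 with fry (4 shared) and 0 with an estimated correlation, and ranged from 16 to 27 (diabetic vehicle replicate 4) with 1 mouse left out. The 12 of liraglutide in diabetic mice became 5 within numbers 1 and 2 (4 shared), 0 with fry and 0 with an estimated correlation, and ranged from 3 (diabetic liraglutide replicate 3; 6 without diabetic liraglutide replicate 4 or diabetic vehicle replicate 2) to 16. The 9 in control mice became 17 within numbers 3 and above (3 shared), 0 with fry and 0 with an estimated correlation, and ranged from 1 (control vehicle replicate 3; 2 without control liraglutide replicate 1, 5 without control vehicle replicate 5) to 19 (control vehicle replicate 2; 18 without control liraglutide replicate 4). Cell type shares gave 0 calls in the settings run, which says nothing of stability for the permutation tests, since a single type could not pass in them.

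The covariance beyond the simulated value was -0.0295 in proximal tubule, -0.0212 in endothelial and -0.008 in distal tubule cells. It became -0.0379, -0.0295 and -0.0169 with the early-late term. With the covariate it was -0.0325 in endothelial and -0.0183 in distal tubule cells. With 1 mouse left out it ranged from -0.0471 to -0.0130, from -0.0376 to -0.00874 and from -0.0161 to -0.00147. Over selected genes the covariance with the mice split, a different quantity with no simulated value subtracted, was -0.396, -0.674 and -0.395 for genes called in diabetes and -0.272, -0.396 and -0.191 for genes chosen in 1 pair.

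Of 56 named genes called in diabetes, 33 passed with each mouse left out; Acsm3, Apoe, Atp5o, Chd3, Cox5b, Edem1, Hadha, Hsp90ab1, Hspa1a, Kap, Kitl, Lpl, Lrg1, Ly6c1, Nfkbia, Odc1, Pdia3, Pdia4, Rgs2, Slc22a28, Slc7a13, Sox4 and Tuba1b did not, most often without diabetic vehicle replicate 3 (18 calls ended), diabetic vehicle replicate 2 (17) or control vehicle replicate 3 (15). No call among them changed its sign. Slc5a2 in proximal tubule cells, not called, had a liraglutide fold of 0.22 that ranged from -0.034 (without diabetic liraglutide replicate 3) to 0.372 (without diabetic liraglutide replicate 1). At the depth, spread and number of mice here, the simulated diabetes comparison recovered 20.9% of 1.5-fold changes in proximal tubule, 7.5% in endothelial and 10.4% in distal tubule cells, and 9 of the 14 cell types held too few cells for an expression test.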

Other observations

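The tests on clock genes and the FOXO targets were added after the data were seen, and the time of day test was chosen after its result was seen.

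Of 18 targets of the FOXO transcription factors 2 rose in proximal tubule cells of diabetic mice and 16 did not pass, 6 of them with negative folds, such as Bcl6 (-0.94), Tob1 (-0.50) and Gadd45a (-0.25). Eif4ebp1, a brake on protein synthesis, rose by 1.23 on the log2 scale (edgeR quasi-likelihood, adjusted p = 0.00879), and Sesn1, an inhibitor of the growth kinase complex mTORC1, by 0.88 (adjusted p = 0.0357). Per1, a gene of the circadian clock, rose by 2.01 (adjusted p = 0.0289), while Per2 and Per3 had folds of -0.57 and -0.35 that did not pass. With liraglutide in diabetic mice the log2 fold changes of Eif4ebp1, Sesn1 and Per1 were -0.56, -0.69 and -0.79, and none of them passed. Irs2, an adaptor of the insulin receptor, had folds of 1.43 in diabetes (adjusted p = 0.0606) and -1.09 with liraglutide, Igfbp1, a liver and kidney gene under insulin control, 1.67 and -2.96, and Pdk4, which shuts off pyruvate oxidation, 1.27 and -1.24, and none of these passed. These genes belong to lists added after the data were seen, so they were chosen knowing that such genes had moved.

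A candidate explanation is that targets of the FOXO transcription factors, which insulin suppresses, follow a lack of insulin in diabetes and more insulin with liraglutide. Insulin was not measured in these data. The mean log2 CPM of 18 such genes was 5.41 ± 0.102 in control vehicle and 5.67 ± 0.207 in diabetic vehicle mice, a difference of 0.261 (exact permutation p = 0.0476, adjusted p = 0.159), with 0.424 within the early and 0.111 within the late numbers. It was 5.30 ± 0.153 in diabetic liraglutide mice, a difference of -0.37 (exact permutation p = 0.0571, adjusted p = 0.159; -0.376 and -0.364 within the early and late numbers), and in control mice the difference with liraglutide was -0.012 (p = 0.841). The second difference missed the threshold set for it, so the hypothesis stays open. A difference in the time of day at collection is another candidate: the mean of clock output genes minus that of morning clock genes differed by 0.529 between diabetic and control vehicle mice (exact permutation p = 0.31; 0.133 and 0.802 within the early and late numbers). With liraglutide the difference was -1.15 in diabetic mice (exact permutation p = 0.114) and 0.882 in control mice (p = 0.0794), so this too stays open.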
